A study of Mus musculus with 38 samples.

How the data were processed

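The series measured whole RNA of the caudal lung lobe of 38 female C57BL/6J mice on Illumina mouse bead arrays, 1 array per animal, after biotin labelling of complementary RNA. Per the labels, 7 control animals were taken at time 0 and 7, 6, 6, 6 and 6 animals 1, 2, 3, 4 and 5 weeks after 30 µl of bleomycin at 1.25 U/ml into the trachea. Deuterated water at 35 µl per g was given, and the labels hold 1 value of new collagen formation per animal, in percent over 7 days. The values analysed are the authors' processed log2 values as deposited, 1 column per array. Their scanner software, background correction and normalization are not stated. The columns share a lowest value of 2.32 (log2 of 5), which held 3.72% of all values, a highest value of 14.88 and medians of 6.38 to 6.39, as after quantile normalization with a floor. The table holds 13481 probes, 52.5% of the 25697 probes of a second table whose 76 per-sample columns (38 of signal and 38 of detection p) match no sample's labels and were not used here. The design, written before the data were examined, put first a background correction and quantile normalization of the scanner table, and named the mapped table on its log2 scale as the choice should that table not map to samples; this second course was taken, with no detection filter.

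Of the probes 12720 had 1 gene symbol, 0 had several and 761 had none. Where a gene had more than 1 probe (2410 genes) the probe with the highest mean over all arrays was kept, which gave 9461 genes. Of these 19 sat at the lowest value on all arrays of at least 1 group. None of 703 pairs of arrays had a correlation over 0.999. The number of arrays, 6 or 7 per group, limits the precision.

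Group means were fitted to all 38 arrays at once with limma 3.58.1 under R 4.3.3 (lmFit and eBayes, 32 residual degrees of freedom), so that every comparison shared 1 estimate of the spread. Each week was compared with control, week 2 with week 1 and week 5 with week 2 by two-sided moderated t tests, and the 5 weekly changes were tested jointly by the moderated F test. New collagen formation was fitted as a covariate across all arrays, and again beside the 6 group means for the relation within time points. P was adjusted by Benjamini and Hochberg over the genes of each comparison, with a threshold of 0.05. New collagen formation itself was compared by exact two-sided permutation tests of the difference in means, adjusted over 7 comparisons, and correlations by 100000 permutations, adjusted over 28 genes. Labels were read with jsonlite 2.0.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

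Gene lists, 38 in all, were fixed from general knowledge before the data were examined. They covered fibrillar collagens, basement membrane, collagen folding and crosslinking, matrix glycoproteins, matrix-degrading proteases, protease inhibitors, the TGF-beta pathway, contractile genes, growth factors, monocyte-derived and resident alveolar macrophages, neutrophils, T and NK cells, B and plasma cells, dendritic cells, mast cells, chemokines and cytokines, complement, interferon response, MHC class II, p53 targets and proliferation. They also covered alveolar type 1 and 2, club and ciliated cells, injury-associated epithelium, endothelium, mesothelium, heart and skeletal muscle, red blood cells, adipocytes, sterol and fatty acid synthesis, oxidative and endoplasmic reticulum stress, the circadian clock, immediate early genes and the Y chromosome. The 36 lists with at least 4 measured genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, two-sided, adjusted over the lists of each comparison. Camera compares a list with the other genes, so a list that did not pass may still have changed. Fry, which tests the genes of a list by themselves, was run beside it. It is given for some lists that did not pass camera at week 1. A cell type's list was used for the genes it holds, and no cell was counted.

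Genes were named by a rule set in the same design. It took the 5 largest rises and falls of each week against control among genes past the threshold with every array of that week on the same side of the control mean, the 4 largest rises and falls of week 2 against week 1 and of week 5 against week 2, and the 6 highest positive and 4 highest negative statistics of each fit on new collagen. It added 16 fixed genes, of which Fn1 and Spp1 were not measured, and up to 3 genes past the threshold with the largest change in each list described. Sirpb1a, Ces1e, Ccl21a, Kng1 and Kng2 have close relatives that their probes may also bind.

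The gene fits were tested on simulated data with 9461 genes of the same group sizes, and camera at the preset correlation on 1 raised and 100 unchanged lists. The simulated genes varied independently, while real genes vary together (estimated correlation 0.517 for the heart and skeletal muscle list). False calls may therefore be more frequent in the real data than simulated, and the check of camera does not cover correlated lists. The permutation tests and camera with an estimated correlation were not simulated. Each simulated comparison between groups changed 67 genes by 1.5-fold, 67 by 2-fold and 66 by 4-fold. The real week 1 comparison called 2145 genes, and the adjusted p depends on the share of changed genes. Recovery may therefore differ in the weeks with many changed genes. Of genes changed 2-fold, 71.6% were recovered in week 1 against control and 61.2% in week 5 against control, with 6.3% and 5.7% of the calls false. In week 2 against week 1 55.2% were recovered and in week 5 against week 2 53.7%, with 7.9% and 5.6% false. Of slopes of 0.1 per percentage point within time points 79.1% were recovered. Alternatives were a trended and robust prior, array quality weights, replicate number as a block, fits on the 2 groups compared, all probes named or not, weeks 1 to 5 alone, each array left out in turn, and camera with an estimated correlation. A filter on a mean log2 of at least 5 and leaving out the least correlated array of each group were chosen after seeing the data.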

Results

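Whole RNA of the caudal lung lobe was hybridised to 38 mouse bead arrays, 1 per female C57BL/6J mouse. The groups were control animals at time 0 (n = 7) and animals killed 1 week (n = 7), 2 weeks (n = 6), 3 weeks (n = 6), 4 weeks (n = 6) and 5 weeks (n = 6) after bleomycin into the trachea. Bleomycin is a standard way of causing lung injury followed by scarring. The labels list controls at time 0 alone, with no bleomycin, and name no vehicle group. A change against control may therefore also hold effects of instillation, age and date of collection. These cannot be told apart from bleomycin here. As far as the labels tell, replicates are separate animals, since each has its own value of new collagen formation. This is given in the labels in percent, with deuterated water given over the 7 days before death. It runs down to -0.11 in a control, so it is an estimate that can fall below 0, and how it was derived is not stated. Each array gave a log2 signal for 13481 probes, of which 1 probe per named gene was tested, 9461 genes in all. The number of arrays limits the precision. Array medians lay between 6.38 and 6.39, and the correlation between 2 arrays lay between 0.903 and 0.983.

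New collagen formation rose within the first week and was still above control at week 5. Controls were at 1.07 ± 0.90% (SD, n = 7), week 1 at 9.35 ± 2.55% (SD, n = 7) and week 2 at 10.2 ± 4.88% (SD, n = 6). Week 3 was at 8.41 ± 6.66% (SD, n = 6), week 4 at 4.53 ± 2.37% (SD, n = 6) and week 5 at 2.64 ± 1.17% (SD, n = 6). Groups were compared by a two-sided exact permutation test of means, adjusted over 7 comparisons. Week 1 exceeded control by 8.27 percentage points (exact p = 0.000583, adjusted p = 0.00204), with 7 of 7 animals above the highest control. Week 2 exceeded it by 9.12 (exact p = 0.000583, adjusted p = 0.00204), with 6 of 6 animals above. Both p are the smallest these group sizes can give. Week 3 exceeded control by 7.34 (exact p = 0.00175, adjusted p = 0.00408, 5 of 6 animals above the highest control). Week 4 exceeded it by 3.45 (exact p = 0.00408, adjusted p = 0.00606, 4 of 6 animals) and week 5 by 1.56 (exact p = 0.0181, adjusted p = 0.0211, 2 of 6 animals). Week 2 and week 1 differed by 0.84 (exact p = 0.695, adjusted p = 0.695). Week 5 fell by 7.55 below week 2 (exact p = 0.00433, adjusted p = 0.00606). Animals ranged from 4.17 to 17.1% within week 2 and from 1.62 to 21.0% within week 3.

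**Figure D1:**
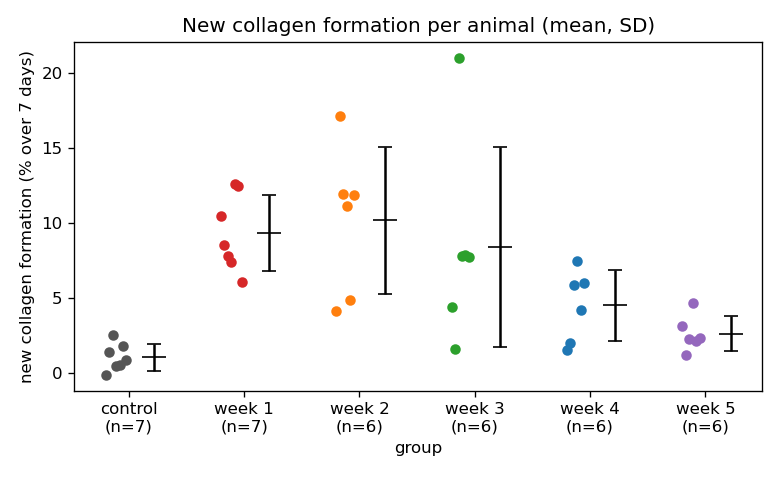
New collagen formation (percent over 7 days, vertical axis) of each animal by group (horizontal axis), with the group mean and SD as a bar and whiskers beside the points. Group means go from 1.07% in controls to 10.2% at week 2 and 2.64% at week 5.

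One week after bleomycin the strongest rises were in genes of macrophages and of the chemokines that draw white cells into tissue. Cxcl9, an interferon-gamma-induced ligand of the chemokine receptor Cxcr3 of T cells, rose by 3.92 ± 0.58, adjusted p = 9.81e-06 (log2 change ± SE, n = 7 and 7). Cxcl10, of the same family, rose by 3.77 ± 0.43. Trem2, a lipid receptor of macrophages, rose by 3.87 ± 0.53, adjusted p = 2.76e-06, and Mmp12, the macrophage elastase, by 3.69 ± 0.64. Together with Atg9b, an autophagy gene (3.41 ± 0.49), these were the 5 largest rises in which 7 of 7 arrays lay above the control mean. In all 2145 of 9461 genes changed in two-sided moderated t tests at an adjusted p under 0.05. Of these 1089 were higher and 1056 lower, and 695 changed by at least 2-fold. The same 7 control arrays served every week, so the weekly comparisons are not independent of each other. The comparisons, gene lists and naming rule were set before the data were examined.

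Of the genes of monocyte-derived and lipid-associated macrophages at week 1, 14 of 18 rose and 0 fell (14 and 0 adjusted over the list alone). The list passed (median 1.53, list adjusted p = 7.28e-12, and adjusted p = 0.0431 with an estimated correlation). Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, rose by 3.01 ± 0.50, Ms4a7 by 2.95 ± 0.49 and Arg1, the arginase of alternatively activated macrophages, by 2.60 ± 0.53. Of chemokine and cytokine genes, 15 of 28 rose and 0 fell (19 and 0 adjusted over the list alone), with the monocyte attractant Ccl7 up by 3.33 ± 0.37. This list passed too (median 1.00, list adjusted p = 4.25e-10, and adjusted p = 0.0431 with an estimated correlation). Of interferon response genes, 8 of 13 rose and 0 fell (8 and 0 adjusted over the list alone). Irf7 (1.72), Isg15 (1.62) and Rsad2 (1.39) led them (median 0.86, list adjusted p = 8.36e-07, and adjusted p = 0.0431 with an estimated correlation). Of T and NK cell genes, 8 of 13 rose and 0 fell (11 and 0 adjusted over the list alone). Cd6 (1.88) and the checkpoint receptor Ctla4 (1.36) were among these (median 0.87, list adjusted p = 8.58e-06, and adjusted p = 0.0803 with an estimated correlation). Ctla4 in 6 of 7 controls and Ccl7 in 4 of 7 sat at the lowest value of the table, so the sizes of these rises are not exact. Of MHC class II presentation genes, 7 of 10 rose and 0 fell (8 and 0 adjusted over the list alone). The invariant chain Cd74 (0.98) and the class II master regulator Ciita (0.90) rose (median 0.79, list adjusted p = 9.54e-07, and adjusted p = 0.0803 with an estimated correlation). Cd22 rose by 1.11 with 3 of 10 B and plasma cell genes (list adjusted p = 0.00666, and adjusted p = 0.344 with an estimated correlation). Ccl17, a chemokine for type 2 helper T cells, rose by 1.88 with 4 of 9 dendritic cell genes (list adjusted p = 0.0472, and adjusted p = 0.113 with an estimated correlation).

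Cell division and DNA damage genes rose in the same week. Of proliferation genes, 22 of 25 rose and 0 fell (23 and 0 adjusted over the list alone). The mitotic kinase Cdk1 (2.24 ± 0.34), thymidine kinase Tk1 (2.16 ± 0.28) and the topoisomerase Top2a (2.13 ± 0.40) were the largest (median 1.45, list adjusted p = 9.78e-19, and adjusted p = 0.0431 with an estimated correlation). Of p53 target genes, 8 of 16 rose and 0 fell (10 and 0 adjusted over the list alone). The cell cycle inhibitor Cdkn1a rose by 1.79 ± 0.21, adjusted p = 4.01e-07, and the cyclin Ccng1 by 1.55 ± 0.18. The p53 list passed (median 0.49, list adjusted p = 5.15e-06, and adjusted p = 0.0431 with an estimated correlation). Of genes of injury-associated epithelium, 9 of 17 rose and 1 fell (10 and 1 adjusted over the list alone). They were led by the tight-junction protein Cldn4 (2.53 ± 0.38), the cornified envelope gene Sprr1a (2.33 ± 0.46) and the stratified-epithelium gene Sfn (1.54 ± 0.35). That list passed at the preset correlation (median 0.52, list adjusted p = 1.96e-05, and adjusted p = 0.0803 with an estimated correlation).

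Matrix genes were also higher at week 1. Tenascin C (Tnc), a matrix glycoprotein of wounds, rose by 2.59 ± 0.41, adjusted p = 2.33e-05. Timp1, the main inducible inhibitor of matrix metalloproteinases, rose by 3.16 ± 0.37, adjusted p = 3.51e-07. Of fibrillar and fibril-associated collagens, 6 of 11 rose and 0 fell (6 and 1 adjusted over the list alone). Col1a2 rose by 1.02 ± 0.34, Col1a1 by 0.98 ± 0.34, adjusted p = 0.0358, and Col3a1 by 0.84 ± 0.30 (median 0.45, list adjusted p = 0.0114, and adjusted p = 0.212 with an estimated correlation). Over 6 alternatives the adjusted p of Col1a1 ranged from 0.0128 to 0.0755. Of basement membrane genes, 7 of 17 rose and 2 fell (7 and 2 adjusted over the list alone). The type IV collagen chains Col4a2 (0.98) and Col4a3 (0.87) were higher and Col4a6 (-0.96) lower (median 0.39, list adjusted p = 0.0135, and adjusted p = 0.254 with an estimated correlation). Of matrix-degrading proteases, 10 of 18 rose and 2 fell (10 and 2 adjusted over the list alone). The collagenase Mmp13 rose by 2.24 ± 0.53, and the aggrecanase Adamts5 was at -1.86 ± 0.34 (median 0.87, list adjusted p = 0.000676, and adjusted p = 0.142 with an estimated correlation). Matrix glycoproteins and proteoglycans had 7 of 18 genes up and 2 down, and the list did not pass (list adjusted p = 0.106, and adjusted p = 0.469 with an estimated correlation). Thrombospondin Thbs2 (1.75) and elastin Eln (1.46) were among the risen. Lox, the crosslinking enzyme of collagen and elastin, rose by 1.31 ± 0.24, while the prolyl hydroxylase subunit P4ha1 was lower (-1.26). Collagen folding and crosslinking genes did not pass as a list (list adjusted p = 0.553, and adjusted p = 0.726 with an estimated correlation).

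Genes of airway, muscle and vessel cells were lower at week 1. Of contractile genes of myofibroblasts and smooth muscle, 0 of 12 rose and 9 fell (0 and 10 adjusted over the list alone). They include smooth muscle myosin Myh11 (-1.68 ± 0.21, adjusted p = 1.18e-06), Lmod1 (-1.25) and smooth muscle actin Acta2 (-0.76 ± 0.15, adjusted p = 0.000358). The contractile list passed (median -0.59, list adjusted p = 1.14e-05, and adjusted p = 0.0431 with an estimated correlation). Of club cell genes, 0 of 13 rose and 6 fell (0 and 8 adjusted over the list alone). The P450 enzyme Cyp4b1 was at -1.10 and the claudin Cldn10 at -1.09 (median -0.83, list adjusted p = 8.13e-05, and adjusted p = 0.136 with an estimated correlation). Of ciliated cell genes, 0 of 12 rose and 1 fell (0 and 1 adjusted over the list alone) (median -0.55, list adjusted p = 0.00174, and adjusted p = 0.304 with an estimated correlation). Of endothelial genes, 0 of 23 rose and 9 fell (0 and 13 adjusted over the list alone). The receptor Tie1 was at -0.95 and the cadherin Cdh5 at -0.70 (median -0.44, list adjusted p = 8.13e-05, and adjusted p = 0.223 with an estimated correlation).

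Heart and skeletal muscle genes, of which lung tissue carries the heart ones in the muscle sleeves of pulmonary veins, were lower at week 1 as well. Of these, 8 of 10 fell, with atrial myosin light chain Myl7 at -2.07 (median -1.54, list adjusted p = 5.33e-05, and adjusted p = 0.169 with an estimated correlation). Of adipocyte genes 4 of 5 fell, among them Thrsp, a regulator of fat synthesis (-2.62 ± 0.51, a bound, since 6 of 7 week 1 arrays sat at the lowest value of the table). The adipocyte list passed at the preset correlation (list adjusted p = 0.00103, and adjusted p = 0.0887 with an estimated correlation). Of red blood cell genes 2 of 5 fell, with the haem enzyme Alas2 at -1.62 (list adjusted p = 0.0311, and adjusted p = 0.212 with an estimated correlation). Other large falls seen in 7 of 7 arrays were those of Asgr1, a glycoprotein receptor (-2.79), and Igfbp3, a carrier of insulin-like growth factors (-2.76 ± 0.47, adjusted p = 6.29e-05). Tmem45b (-2.36, a bound, with 4 of 7 week 1 arrays at the lowest value) and Hrc, a calcium-binding protein of muscle (-2.30), also fell in 7 of 7. Of alveolar type 2 cell genes 2 of 19 rose and 1 fell (list adjusted p = 0.939). Their surfactant gene Sftpc was at -0.22 (adjusted p = 0.331).

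**Figure D2:**
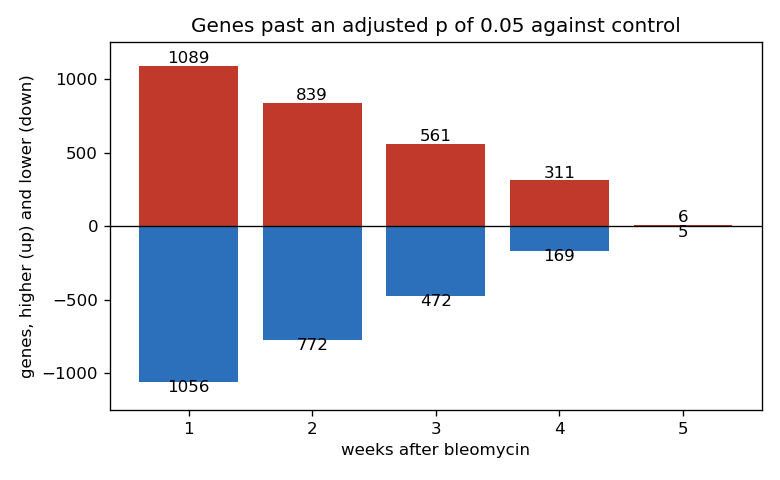
Number of genes (vertical axis) past an adjusted p of 0.05 against control in each week (horizontal axis), with higher genes above 0 and lower genes under it. The total goes from 2145 at week 1 to 11 at week 5.

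At week 2 macrophage markers were among the largest rises, and matrix genes were higher too. Mmp12 rose by 3.26 ± 0.67, adjusted p = 0.00155 (log2 change ± SE, n = 6 and 7). Trem2 rose by 3.06 ± 0.55, Ms4a7 by 2.82 ± 0.51, and Itm2a, a membrane protein of activated T cells and of mesenchyme, by 2.64 ± 0.40. The probe of Sirpb1a, which near-identical family members make uncertain, rose by 3.21 ± 0.54. In all 1611 genes changed, 839 higher and 772 lower, 487 of them by at least 2-fold. Of macrophage genes, 14 of 18 rose and 1 fell (14 and 1 adjusted over the list alone), and the list passed at the preset correlation (median 1.27, list adjusted p = 2.06e-09, and adjusted p = 0.105 with an estimated correlation). Of matrix glycoproteins and proteoglycans, 9 of 18 rose and 0 fell (9 and 0 adjusted over the list alone). Thbs2 rose by 2.38 ± 0.52, Tnc by 2.14 ± 0.43 and Eln by 1.53 ± 0.33 (median 0.64, list adjusted p = 6.17e-05, and adjusted p = 0.105 with an estimated correlation). Of basement membrane genes, 8 of 17 rose and 2 fell (10 and 2 adjusted over the list alone). The largest rises were those of Col4a3 (1.56), Col4a5 (1.16) and Col4a2 (1.13) (median 0.52, list adjusted p = 0.000131, and adjusted p = 0.105 with an estimated correlation). Among fibrillar collagens 2 of 11 rose, Col5a1 (0.61) and Col6a1 (0.41) (median 0.41, list adjusted p = 0.0101, and adjusted p = 0.171 with an estimated correlation). Col1a1 stood at 0.80 (adjusted p = 0.119). Of matrix-degrading proteases, 7 of 18 rose and 2 fell (8 and 2 adjusted over the list alone), with Mmp13 at 2.12. This list passed at the preset correlation (median 0.58, list adjusted p = 0.00105, and adjusted p = 0.137 with an estimated correlation). In the TGF-beta pathway 5 of 22 rose and 2 fell (list adjusted p = 0.026, and adjusted p = 0.171 with an estimated correlation). They included the activin antagonist Fst (1.59) and Itgb6 (0.97), part of an integrin that activates latent TGF-beta.

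White cell, division and damage genes were also higher at week 2. Of proliferation genes, 15 of 25 rose and 0 fell (15 and 0 adjusted over the list alone). Cdk1 was at 1.67 and the spindle protein Prc1 at 1.59 (median 1.05, list adjusted p = 7.3e-10, and adjusted p = 0.105 with an estimated correlation). Of chemokine and cytokine genes, 9 of 28 rose and 0 fell (13 and 0 adjusted over the list alone). Cxcl10 was at 2.36 and Ccl6 at 2.17 (median 0.63, list adjusted p = 5.94e-06, and adjusted p = 0.11 with an estimated correlation). Of MHC class II genes, 8 of 10 rose and 0 fell (8 and 0 adjusted over the list alone), and the list passed (median 0.56, list adjusted p = 5.24e-06, and adjusted p = 0.105 with an estimated correlation). T and NK cell genes had 7 of 13 up (list adjusted p = 3.2e-05, and adjusted p = 0.105 with an estimated correlation). B and plasma cell genes had 5 of 10 up, including Pou2af1, a coactivator of antibody-making cells (1.21). Their list passed at the preset correlation (list adjusted p = 7.58e-05, and adjusted p = 0.152 with an estimated correlation). The p53 targets had 7 of 16 genes up, Cdkn1a by 1.35 ± 0.22 (list adjusted p = 0.000153, and adjusted p = 0.105 with an estimated correlation). Interferon response genes had 4 of 13 up (list adjusted p = 0.00248, and adjusted p = 0.135 with an estimated correlation).

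The falls at week 2 were in the lining of the airways, in muscle and in the clock. Of club cell genes, 0 of 13 rose and 9 fell (0 and 10 adjusted over the list alone), with the secretoglobin Scgb3a1 at -1.58 ± 0.44 (median -0.75, list adjusted p = 7.59e-07, and adjusted p = 0.105 with an estimated correlation). Scgb1a1, the most abundant secretoglobin of these cells, was at -0.13 (adjusted p = 0.513). Of ciliated cell genes, 0 of 12 rose and 8 fell (0 and 12 adjusted over the list alone), including the axonemal tektin Tekt1 (-1.07). The ciliated list passed at the preset correlation (median -0.75, list adjusted p = 5.94e-06, and adjusted p = 0.135 with an estimated correlation). Of contractile genes, 0 of 12 rose and 7 fell (0 and 8 adjusted over the list alone), with Acta2 at -0.67 ± 0.16, adjusted p = 0.00424 (median -0.65, list adjusted p = 5.09e-05, and adjusted p = 0.105 with an estimated correlation). Heart and skeletal muscle genes had 7 of 10 lower (list adjusted p = 2.86e-05, and adjusted p = 0.135 with an estimated correlation). Of circadian clock genes, 0 of 13 rose and 7 fell (0 and 7 adjusted over the list alone). Nr1d1 (-1.90 ± 0.32, adjusted p = 0.000452) and Nr1d2 (-1.54), nuclear receptors that repress Arntl, and Cry2 (-1.42) led them (median -1.05, list adjusted p = 0.000166, and adjusted p = 0.105 with an estimated correlation). The largest falls seen in 6 of 6 arrays were those of Hamp, the iron hormone hepcidin (-3.27), Asgr1 (-2.53) and Bex2 (-2.30). Ces1e, a carboxylesterase with close relatives (-2.15), and Lypd2 (-2.14) followed. The total was 1032 without week 2 replicate 2, the animal with 17.1% new collagen, and 1068 without week 2 replicate 4.

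At week 3 the same macrophage markers were again among the large rises. Trem2 rose by 3.22 ± 0.55, adjusted p = 0.0011 (log2 change ± SE, n = 6 and 7). Mmp12 rose by 3.04 ± 0.67, Ms4a7 by 2.71 ± 0.51 and Sirpb1a by 2.87 ± 0.54. Kininogen Kng1, a precursor of bradykinin whose probe may also bind Kng2, rose by 2.82 ± 0.77. In all 1033 genes changed, 561 higher and 472 lower, 317 of them by at least 2-fold. Of macrophage genes, 11 of 18 rose and 1 fell (12 and 1 adjusted over the list alone) (median 1.01, list adjusted p = 4.35e-08, and adjusted p = 0.125 with an estimated correlation). Of fibrillar collagens, 3 of 11 rose and 0 fell (3 and 0 adjusted over the list alone). Col1a1 rose by 1.15 ± 0.36, adjusted p = 0.0348, and Col6a2 by 0.72 (median 0.49, list adjusted p = 0.0113, and adjusted p = 0.204 with an estimated correlation). Over 6 alternatives the adjusted p ranged from 0.018 to 0.126 for Col1a1 and from 0.0204 to 0.0547 for Col6a2, and the other type I chain, Col1a2, was at 0.49 (adjusted p = 0.388). Of basement membrane genes, 7 of 17 rose and 0 fell (9 and 1 adjusted over the list alone). Col4a3 rose by 1.52 ± 0.24, Col4a2 by 1.30 ± 0.18 and the epithelial laminin chain Lamb3 by 1.16 ± 0.19 (median 0.49, list adjusted p = 7.87e-06, and adjusted p = 0.118 with an estimated correlation). Of matrix glycoproteins 7 of 18 rose (list adjusted p = 0.000215, and adjusted p = 0.163 with an estimated correlation). Thbs2 was at 1.76, Tnc at 1.73 and the microfibril protein Mfap5 at 1.46. Of matrix-degrading proteases 4 of 18 rose and 1 fell (list adjusted p = 0.00811, and adjusted p = 0.208 with an estimated correlation). In the TGF-beta pathway 4 of 22 rose, among them Tgfb1, the cytokine itself (0.83), and the list did not pass (list adjusted p = 0.0523, and adjusted p = 0.234 with an estimated correlation).

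Lymphocyte genes stayed above control at week 3. Of B and plasma cell genes, 6 of 10 rose and 0 fell (7 and 0 adjusted over the list alone). Pou2af1 was at 1.34, Cd79a, a chain of the B cell receptor, at 1.25 (adjusted p from 0.0146 to 0.121 over 6 alternatives) and Mzb1, a protein of antibody-secreting cells, at 1.23. The list passed at the preset correlation (median 0.87, list adjusted p = 3.13e-05, and adjusted p = 0.163 with an estimated correlation). T and NK cell genes had 6 of 13 up (list adjusted p = 3.11e-05, and adjusted p = 0.125 with an estimated correlation). MHC class II genes had 6 of 10 up (list adjusted p = 5.58e-07, and adjusted p = 0.125 with an estimated correlation), and interferon response genes 2 of 13 (list adjusted p = 0.0126, and adjusted p = 0.204 with an estimated correlation). Of chemokine and cytokine genes, 11 of 28 rose and 1 fell (13 and 1 adjusted over the list alone) (median 0.56, list adjusted p = 2.73e-06, and adjusted p = 0.125 with an estimated correlation). The p53 targets had 4 of 16 up (list adjusted p = 0.00438, and adjusted p = 0.163 with an estimated correlation). Proliferation genes had 3 of 25 up, with Tk1 at 1.17 (list adjusted p = 1.71e-05, and adjusted p = 0.204 with an estimated correlation).

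Airway genes were lower again at week 3. Of club cell genes, 0 of 13 rose and 8 fell (0 and 10 adjusted over the list alone), with Scgb3a1 at -1.55 (median -0.74, list adjusted p = 4.35e-08, and adjusted p = 0.118 with an estimated correlation). Of ciliated cell genes, 0 of 12 rose and 7 fell (0 and 12 adjusted over the list alone), with Ccdc113 at -1.27 (median -0.91, list adjusted p = 1.17e-07, and adjusted p = 0.125 with an estimated correlation). Contractile genes had 7 of 12 lower, Acta2 among them (-0.68 ± 0.16, adjusted p = 0.00578), and the list passed at the preset correlation (list adjusted p = 2.53e-05, and adjusted p = 0.118 with an estimated correlation). Heart and skeletal muscle genes had 5 of 10 lower (list adjusted p = 3.92e-05, and adjusted p = 0.163 with an estimated correlation), and adipocyte genes 1 of 5 (list adjusted p = 0.0204, and adjusted p = 0.204 with an estimated correlation). Of alveolar type 2 cell genes 3 of 19 rose, with the lysosomal protein Lamp3 at 0.95 (list adjusted p = 0.0324, and adjusted p = 0.353 with an estimated correlation). Ager, the receptor that marks alveolar type 1 cells, rose by 0.47 ± 0.14, adjusted p = 0.03, with adjusted p from 0.0191 to 0.153 over 6 alternatives. Among the largest falls were those of Asgr1 (-2.30), Prom2 (-1.99), Bex2 (-1.92), Iqcd (-1.91, a bound, with 4 of 6 week 3 arrays at the lowest value) and Rptn (-1.91). The total was 388 genes without week 3 replicate 3, the animal with 21.0% new collagen, and 630 without control replicate 2.

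At week 4, macrophage, kininogen and type IV collagen genes were still above control. Kng1 rose by 2.73 ± 0.77, adjusted p = 0.0337 (log2 change ± SE, n = 6 and 7). Sirpb1a rose by 2.68 ± 0.54, Ms4a7 by 2.56 ± 0.51, Kng2 by at least 2.48 ± 0.60 (5 of 7 controls at the lowest value) and Mmp12 by 2.35 ± 0.67. Over 6 alternatives the adjusted p ranged from 0.0147 to 0.0625 for Kng1 and from 0.0113 to 0.0801 for Mmp12. In all 480 genes changed, 311 higher and 169 lower, 148 of them by at least 2-fold. Of macrophage genes, 8 of 18 rose and 0 fell (13 and 1 adjusted over the list alone) (median 0.84, list adjusted p = 5.7e-07, and adjusted p = 0.157 with an estimated correlation). Col4a3 rose by 1.40 ± 0.24, adjusted p = 0.00372, Col4a4 by 0.90 (adjusted p from 0.0119 to 0.0836 over 6 alternatives) and Col4a2 by 0.89. Basement membrane genes had 6 of 17 up (list adjusted p = 0.00807, and adjusted p = 0.287 with an estimated correlation). None of 11 fibrillar collagens passed (list adjusted p = 0.555, and adjusted p = 0.781 with an estimated correlation), Col1a1 standing at 0.27 (adjusted p = 0.719). None of 25 proliferation genes passed either (list adjusted p = 0.111, and adjusted p = 0.715 with an estimated correlation). T and NK cell genes had 4 of 13 up (list adjusted p = 4.85e-06, and adjusted p = 0.113 with an estimated correlation). B and plasma cell genes had 3 of 10 up (list adjusted p = 9.76e-06, and adjusted p = 0.157 with an estimated correlation), and MHC class II genes 5 of 10 (list adjusted p = 3.97e-07, and adjusted p = 0.113 with an estimated correlation). Chemokine and cytokine genes had 4 of 28 up and 1 down (list adjusted p = 3.96e-05, and adjusted p = 0.157 with an estimated correlation). Alveolar type 2 cell genes had 4 of 19 up (list adjusted p = 0.00703, and adjusted p = 0.34 with an estimated correlation).

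Of contractile genes at week 4, 0 of 12 rose and 5 fell (0 and 9 adjusted over the list alone). Myh11 was at -1.12 ± 0.22 and the enteric actin Actg2 at -0.91 ± 0.20 (median -0.49, list adjusted p = 3.97e-07, and adjusted p = 0.0498 with an estimated correlation). Of club cell genes, 0 of 13 rose and 4 fell (0 and 8 adjusted over the list alone), with Scgb3a1 at -1.68 ± 0.44 (median -0.56, list adjusted p = 5.7e-07, and adjusted p = 0.113 with an estimated correlation). Ciliated cell genes had 2 of 12 lower (list adjusted p = 5.77e-06, and adjusted p = 0.157 with an estimated correlation). Clock genes had 3 of 13 lower, with Nr1d1 at -1.22 (list adjusted p = 0.000817, and adjusted p = 0.113 with an estimated correlation). Hamp (-2.14), Lypd2 (-1.76), Prom2 (-1.69) and Ces1e (-1.66) were among the largest falls. Without the least correlated arrays 4 of these genes did not pass, their adjusted p over 6 alternatives ranging from 0.0191 to 0.111 for Hamp, 0.0187 to 0.148 for Lypd2, 0.0169 to 0.114 for Scgb3a1 and 0.0108 to 0.123 for Nr1d1. The week 4 total moved with single animals, to 98 genes without week 4 replicate 4, which had the highest new collagen of that week.

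By week 5, 11 genes passed against control, 6 higher and 5 lower. Col4a3, a chain of the alveolar basement membrane, rose by 1.12 ± 0.24, adjusted p = 0.0429 (log2 change ± SE, n = 6 and 7). Ccl21a, a lymph node chemokine whose probe near-identical gene copies make uncertain, rose by 1.04 ± 0.20, adjusted p = 0.0214. Thrap3 (1.38, a bound, with 5 of 7 controls at the lowest value), Rab1b (1.34) and Ptp4a3 (0.70) were the other large rises. The heat shock protein Hsph1 (-1.12), Heatr3 (-0.82), Wdr5 (-0.79) and the cyclic AMP modulator Crem (-0.73) were lower, and Mrpl51 fell by 1.00. Over the alternatives the adjusted p ranged from 0.014 to 0.0504 for Thrap3 and from 0.00516 to 0.0504 for Crem. In limma 1254 genes had an unadjusted p under 0.05. The count moved from 2 genes without week 5 replicate 5 to 130 without week 5 replicate 2.

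At week 5, 16 of 36 lists passed at the preset correlation and 0 of 36 with an estimated correlation. B and plasma cell genes were higher, 9 of 10 when adjusted over the list alone and 0 over all genes (median 0.93, list adjusted p = 1.96e-09, and adjusted p = 0.144 with an estimated correlation). Macrophage genes had 9 of 18 up adjusted over the list alone (median 0.55, list adjusted p = 4.26e-06, and adjusted p = 0.284 with an estimated correlation). MHC class II genes had 5 of 10 up in the same way (median 0.44, list adjusted p = 1.41e-06, and adjusted p = 0.204 with an estimated correlation), and T and NK cell genes 6 of 13 (median 0.59, list adjusted p = 4.46e-05, and adjusted p = 0.224 with an estimated correlation). Contractile genes had 7 of 12 lower adjusted over the list alone (median -0.38, list adjusted p = 4.46e-05, and adjusted p = 0.144 with an estimated correlation). Club cell genes (median -0.42, list adjusted p = 0.000132, and adjusted p = 0.284 with an estimated correlation) were lower as a list. So were ciliated cell genes (median -0.42, list adjusted p = 0.000263, and adjusted p = 0.347 with an estimated correlation). Alveolar type 2 cell genes were higher as a list, with 1 of 19 up adjusted over the list alone (median 0.30, list adjusted p = 0.000196, and adjusted p = 0.284 with an estimated correlation).

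**Figure D3:**
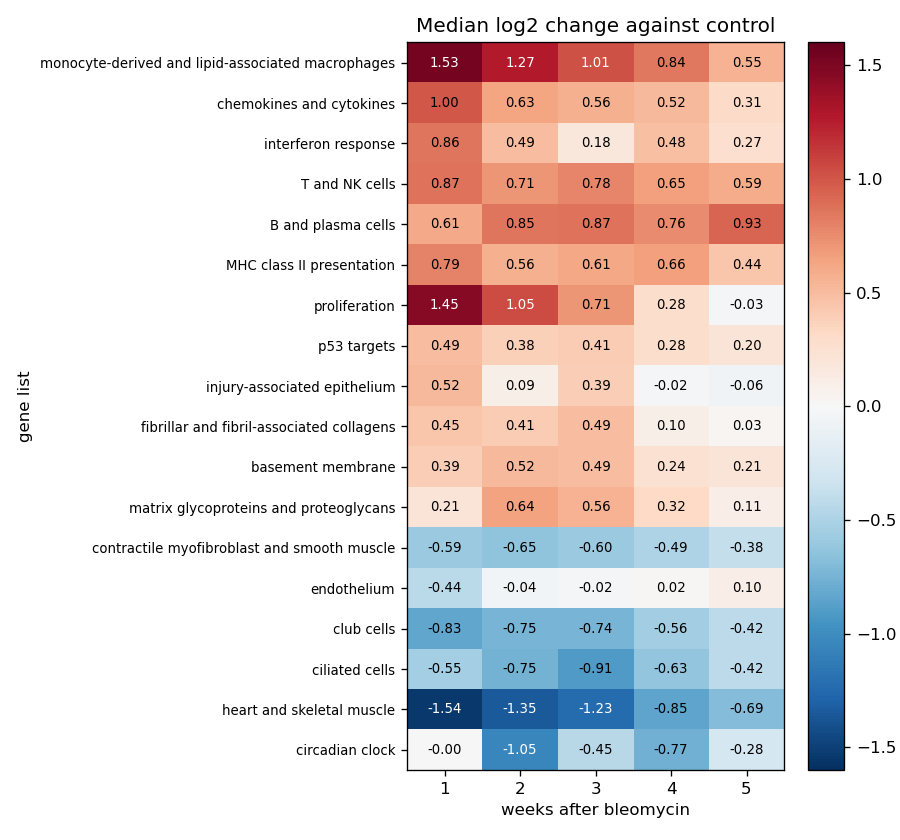
Median log2 change against control of the measured genes of 18 gene lists (vertical axis) in weeks 1 to 5 (horizontal axis), coloured from blue for lower to red for higher, with the value printed in each cell. Macrophage genes go from 1.53 at week 1 to 0.55 at week 5, and contractile genes from -0.59 to -0.38.

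Between weeks 1 and 2, 59 genes differed, 34 higher and 25 lower at week 2. The count moved from 28 genes without week 2 replicate 1 to 136 without week 2 replicate 3, and was 9 with only the 2 groups fitted. Of chemokine and cytokine genes, 1 of 28 rose and 2 fell (2 and 7 adjusted over the list alone) (median -0.47, list adjusted p = 0.000315, and adjusted p = 0.263 with an estimated correlation). The chemokines Ccl7 (-2.52 ± 0.39, adjusted p = 0.000452, log2 change ± SE, n = 6 and 7), Ccl17 (-2.16 ± 0.43, adjusted p = 0.00729) and Ccl2 (-1.12 ± 0.27, not an exact size, with 3 of 6 week 2 arrays at the lowest value) were lower at week 2. So was Cldn4 (-1.71 ± 0.39). The growth factor carrier Igfbp3 rose by 2.39 ± 0.49, adjusted p = 0.0107. C1qtnf3 (1.85), Fam124b (at least 1.65, with 6 of 7 week 1 arrays at the lowest value) and Pcolce2, an enhancer of procollagen processing (1.46), rose too. Each of 6 of these genes lost the threshold in at least 1 of 5 or 6 alternatives. Their adjusted p ranged from 0.012 to 0.0798 for Ccl2, 0.0165 to 0.117 for Cldn4, 0.0061 to 0.107 for Igfbp3, 0.0105 to 0.0559 for C1qtnf3, 0.0116 to 0.0908 for Fam124b and 0.00372 to 0.111 for Pcolce2. The clock output gene Dbp was lower by the largest amount (-3.12 ± 0.41, adjusted p = 4.98e-05), and among clock genes Nr1d1 (-1.94) and Nr1d2 (-1.89) followed. Of clock genes, 1 of 13 rose and 3 fell (3 and 6 adjusted over the list alone) (median -0.44, list adjusted p = 0.00323, and adjusted p = 0.173 with an estimated correlation). Endothelial genes were higher at week 2 as a list, with Emcn at 0.55 (median 0.37, list adjusted p = 7.67e-09, and adjusted p = 0.136 with an estimated correlation). Proliferation genes were lower as a list (median -0.58, list adjusted p = 1.9e-08, and adjusted p = 0.173 with an estimated correlation). The same held for injury-associated epithelium (median -0.33, list adjusted p = 4.66e-05, and adjusted p = 0.136 with an estimated correlation), interferon response (median -0.41, list adjusted p = 0.000201, and adjusted p = 0.136 with an estimated correlation) and dendritic cells (median -0.64, list adjusted p = 0.00181, and adjusted p = 0.048 with an estimated correlation).

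From week 2 to week 5 cell division genes fell back. Of the 24 genes that differed, 21 were lower at week 5. Cdk1 (-2.16 ± 0.37, adjusted p = 0.00431, log2 change ± SE, n = 6 and 6), Spag5 (-2.15), Prc1 (-1.90 ± 0.30, adjusted p = 0.00257) and Gtse1 (-1.89), which act in mitosis, fell most. Of proliferation genes, 0 of 25 rose and 4 fell (0 and 15 adjusted over the list alone) (median -0.82, list adjusted p = 1.17e-17, and adjusted p = 0.0946 with an estimated correlation). Lox (-1.34 ± 0.26, adjusted p = 0.0169), Col5a1 (-0.90 ± 0.21, adjusted p = 0.0453, from 0.0147 to 0.0511 over 6 alternatives) and Serpina3n (-1.05 ± 0.24) were lower. So was Ccn4, a matricellular Wnt target (-1.54 ± 0.34, adjusted p = 0.0398). Matrix glycoproteins fell as a list (9 of 18 adjusted over the list alone, list adjusted p = 1.59e-05, and adjusted p = 0.227 with an estimated correlation). Fibrillar collagens did as well (list adjusted p = 0.00144, and adjusted p = 0.243 with an estimated correlation). The 3 genes higher at week 5 were Nr1d1 (1.80), Thrap3 (1.37, a bound, with 4 of 6 week 2 arrays at the lowest value) and Cry2 (1.03). The count moved from 3 genes without week 2 replicate 2 to 176 without week 2 replicate 5. Over all 5 weeks tested jointly, 1713 genes passed the moderated F test. This is fewer than the 2145 of week 1 against control, so it is no count of all genes changed at some time point.

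Expression was also set against each animal's new collagen formation, over all 38 arrays. Eln rose by 0.15 ± 0.01, adjusted p = 1.3e-09 per percentage point of new collagen (log2 ± SE). Tnc rose by 0.20 ± 0.02, adjusted p = 8.93e-09, Ccn4 by 0.16 ± 0.02, adjusted p = 8.58e-09 and the membrane-bound collagenase Mmp14 by 0.12 ± 0.01, adjusted p = 1.17e-08. Lhfpl2 (0.13) and the calcineurin regulator Rcan1 (0.07) followed. Negative slopes were led by the glutathione transferase Gsta3 (-0.09 ± 0.01, adjusted p = 1.03e-08), Snhg11 (-0.13), myoglobin Mb (-0.14) and the aldehyde oxidase Aox3 (-0.11 ± 0.01, adjusted p = 1.44e-08). In all 3068 genes followed new collagen formation, 1458 upward and 1610 downward, and 1643 did over the 31 arrays of weeks 1 to 5 alone. This fit holds no group means, so it mixes differences between time points with those within them. A gene that changed after bleomycin with a similar time course is counted too. With the group means beside it 738 genes passed. Of matrix glycoproteins, 11 of 18 rose and 2 fell (13 and 3 adjusted over the list alone) (median 0.06, list adjusted p = 7.5e-06, and adjusted p = 0.0408 with an estimated correlation). Of matrix-degrading proteases, 12 of 18 rose and 2 fell (12 and 2 adjusted over the list alone) (median 0.08, list adjusted p = 1.75e-05, and adjusted p = 0.0408 with an estimated correlation).

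Other lists followed new collagen formation over all arrays, in the same fit without group means. Proliferation had 21 of 25 genes upward (list adjusted p = 1.04e-14, and adjusted p = 0.0408 with an estimated correlation). Macrophage genes had 14 of 18 (list adjusted p = 8.6e-11, and adjusted p = 0.0408 with an estimated correlation) and fibrillar collagens 7 of 11 (list adjusted p = 0.000187, and adjusted p = 0.0408 with an estimated correlation). Basement membrane had 10 of 17 (list adjusted p = 0.000111, and adjusted p = 0.0408 with an estimated correlation), and collagen folding and crosslinking 6 of 17 (list adjusted p = 0.00306, and adjusted p = 0.0408 with an estimated correlation). In the TGF-beta pathway 12 of 22 genes went upward (list adjusted p = 0.0058, and adjusted p = 0.0408 with an estimated correlation). Club cell genes had 9 of 13 downward (list adjusted p = 6.94e-07, and adjusted p = 0.0408 with an estimated correlation). Heart and skeletal muscle had 8 of 10 downward (list adjusted p = 6.94e-07, and adjusted p = 0.0408 with an estimated correlation) and adipocytes 5 of 5 (list adjusted p = 0.000213, and adjusted p = 0.0408 with an estimated correlation).

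For 28 genes named by rule the correlation with new collagen formation was also computed across arrays, with permutation p adjusted over the 28. Across arrays, r and rho also hold the differences between groups, and their permutations ran across groups. Eln had a Pearson r of 0.875 (permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 1.4e-05). Its Spearman rho was 0.872 (permutation p = 1e-05, adjusted p = 1.56e-05), and r was 0.86 without the 2 animals farthest from the median. Col1a1 had r = 0.625 (permutation p = 4e-05, adjusted p = 5.09e-05) and rho = 0.61 (permutation p = 7e-05, adjusted p = 9.8e-05), and 0.552 without those 2 animals. Acta2 went the other way, with r = -0.373 (permutation p = 0.0206, adjusted p = 0.024) and rho = -0.509 (permutation p = 0.00121, adjusted p = 0.00147), and -0.565 without them. After each group's mean was taken off both measures, r was 0.743 for Eln (permutation p = 2e-05, adjusted p = 9.33e-05). It was 0.449 for Col1a1 (permutation p = 0.00869, adjusted p = 0.0111) and 0.167 for Acta2 (permutation p = 0.404, adjusted p = 0.452). Eln was picked by rule for its large statistic in these same data, and its r was 0.993 within week 3 and -0.243 within week 5.

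**Figure D4:**
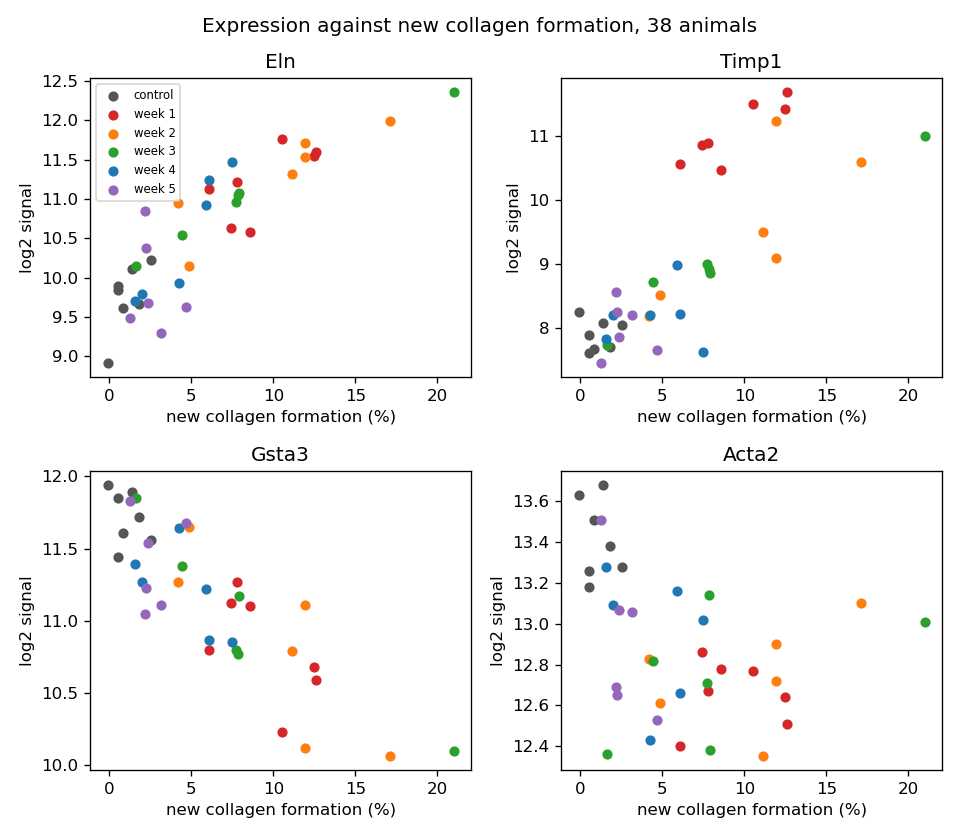
Log2 signal of Eln, Timp1, Gsta3 and Acta2 (vertical axis) against new collagen formation (percent, horizontal axis) in 38 animals, coloured by group, 1 point per animal. Eln has a Pearson r of 0.875, Timp1 of 0.792, Gsta3 of -0.855 and Acta2 of -0.373.

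With the 6 group means fitted beside it, new collagen formation was followed by matrix and protease genes as well. Timp1 rose by 0.15 ± 0.02, adjusted p = 0.000102 per percentage point (log2 ± SE). Its r was 0.872, 0.793 and 0.985 within weeks 1, 2 and 3, and -0.058, 0.094 and -0.056 within controls and weeks 4 and 5. Ccn4 rose by 0.13 ± 0.02, adjusted p = 0.000102, Mmp14 by 0.12 ± 0.02 (r = 0.074 within week 1) and the replication licensing factor Cdt1 by 0.10 ± 0.01, adjusted p = 0.000102. The adaptor Dok2 (0.10) and Rcan1 (0.07) rose, while Glb1l2 (-0.09) and the protease Tmprss13 (-0.13) fell. Gsta3 (-0.09 ± 0.01, adjusted p = 0.000259) and the fat cell hormone Adipoq (-0.22 ± 0.04, adjusted p = 0.000259) fell too. In all 738 genes passed, 349 upward and 389 downward. Of matrix glycoproteins, 8 of 18 rose and 0 fell (10 and 1 adjusted over the list alone). Thbs2 was at 0.18 and Tnc at 0.16 (median 0.05, list adjusted p = 1.14e-06, and adjusted p = 0.0275 with an estimated correlation). Of matrix-degrading proteases, 7 of 18 rose and 0 fell (8 and 0 adjusted over the list alone) (median 0.06, list adjusted p = 6.28e-06, and adjusted p = 0.0275 with an estimated correlation). In the TGF-beta pathway 5 of 22 rose and 1 fell (list adjusted p = 0.000498, and adjusted p = 0.0275 with an estimated correlation). Of collagen folding and crosslinking genes 3 of 17 rose (list adjusted p = 0.000647, and adjusted p = 0.0275 with an estimated correlation).

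Macrophage genes within time points had 10 of 18 upward and 1 downward, with Arg1 at 0.19 ± 0.04, adjusted p = 0.00138. Their list passed at the preset correlation (list adjusted p = 2.22e-08, and adjusted p = 0.0562 with an estimated correlation). Proliferation genes had 9 of 25 upward (list adjusted p = 2.7e-10, and adjusted p = 0.0498 with an estimated correlation). Of club cell genes, 0 of 13 rose and 6 fell (0 and 9 adjusted over the list alone) (median -0.05, list adjusted p = 2.06e-06, and adjusted p = 0.0275 with an estimated correlation). Of adipocyte genes 2 of 5 fell (list adjusted p = 0.000181, and adjusted p = 0.0275 with an estimated correlation). None of 12 contractile genes passed (list adjusted p = 0.456, and adjusted p = 0.714 with an estimated correlation), and none of 13 T and NK cell genes (list adjusted p = 0.317, and adjusted p = 0.675 with an estimated correlation). The count of 738 was 85 without week 3 replicate 3 and 480 without week 3 replicate 2. It was 17 without week 3 replicate 3 and week 2 replicate 2 together.

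Growth factor and stress lists did not pass at week 1, while single genes of them did. Among insulin-like and other growth factors 6 of 21 rose and 5 fell at week 1 (list adjusted p = 0.91, and adjusted p = 0.951 with an estimated correlation). The Wnt antagonist Sfrp1 was at 2.12 and Ccn4 at 1.74. Among protease inhibitors 3 of 11 rose and 3 fell (list adjusted p = 0.392, and adjusted p = 0.442 with an estimated correlation). The acute-phase serpin Serpina3n rose by 1.99 ± 0.22, adjusted p = 1.85e-07, and Serpinb6b by 0.85. Oxidative stress genes had 4 of 17 up and 6 down (list adjusted p = 0.663, and adjusted p = 0.686 with an estimated correlation). The cystine transporter Slc7a11 (at least 2.01 ± 0.38, adjusted p = 0.000238, with 4 of 7 controls at the lowest value) and haem oxygenase Hmox1 (1.53) were higher and Aox3 (-1.42) lower. At week 4 the oxidative stress list passed at the preset correlation, and 0 of 17 rose and 2 fell (0 and 4 adjusted over the list alone) (median -0.34, list adjusted p = 0.0302, and adjusted p = 0.113 with an estimated correlation). Of 7 neutrophil genes, Lcn2, an iron-trapping protein that epithelium also makes, rose by 2.80 ± 0.30, adjusted p = 1.06e-07, and G0s2 was at -1.07. The neutrophil list did not pass (list adjusted p = 0.068, and adjusted p = 0.223 with an estimated correlation). By fry in 1 direction, neutrophils and protease inhibitors passed at week 1 (adjusted p = 0.00113 for both). Growth factors (adjusted p = 0.918) and oxidative stress (adjusted p = 0.145) did not. With both directions allowed these last lists passed by fry (adjusted p = 4.34e-07 and 4.17e-05).

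Several cell and pathway lists did not pass at week 1. They were resident alveolar macrophages (list adjusted p = 0.392, and adjusted p = 0.645 with an estimated correlation), alveolar type 1 cells (list adjusted p = 0.366, and adjusted p = 0.686 with an estimated correlation) and mesothelium (list adjusted p = 0.0897, and adjusted p = 0.469 with an estimated correlation). Complement (list adjusted p = 0.737, and adjusted p = 0.821 with an estimated correlation) and endoplasmic reticulum stress (list adjusted p = 0.874, and adjusted p = 0.919 with an estimated correlation) did not pass. Immediate early genes (list adjusted p = 0.91, and adjusted p = 0.951 with an estimated correlation) and sterol and fatty acid synthesis (list adjusted p = 0.91, and adjusted p = 0.951 with an estimated correlation) did not either. In the TGF-beta pathway 7 of 22 rose and 2 fell, and the list did not pass (list adjusted p = 0.152, and adjusted p = 0.423 with an estimated correlation). By fry in 1 direction the TGF-beta list passed (adjusted p = 0.0187), and the lists named before it here did not. The lists of mast cells, basophils and eosinophils and of the Y chromosome held fewer than 4 measured genes and were not tested.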

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

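The tests of the contractile genes and the test of collection at another time of day were chosen after the results were seen, and the remaining tests of this part were set before.

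In 302 groups of 6 or 7 samples (new collagen formation and each named gene in the groups compared) 19 had an extreme sample whose gap to its neighbour took an unusually large share of the group's range, and chance marks about 1 in 20 groups, so these 19 are near what chance gives. With that share in parentheses, week 3 replicate 3 was the highest for new collagen formation (0.677), Col4a2 (0.755) and Tk1 (0.728), control replicate 1 was the lowest for Alas2 (0.575) and Isg15 (0.628), control replicate 1 was the highest for Ccl7 (0.691) and Lmod1 (0.59), week 1 replicate 2 was the lowest for Cdk1 (0.701) and Tk1 (0.612) and week 1 replicate 5 was the lowest for Col4a6 (0.665). Control replicate 4 was the highest for Ctla4 (1), week 1 replicate 4 was the highest for Cyp4b1 (0.613), week 1 replicate 2 was the highest for Thrsp (1), week 2 replicate 5 was the lowest for Cdk1 (0.627) and week 2 replicate 2 was the highest for Itgb6 (0.626). Control replicate 5 was the lowest for Nr1d1 (0.606), control replicate 3 was the highest for Kng2 (0.899), week 4 replicate 4 was the lowest for Scgb3a1 (0.659) and week 1 replicate 6 was the highest for Fam124b (1). For Ctla4, Thrsp and Fam124b the share of 1 is fixed by the lowest value of the table, where 6 of 7 arrays sat.

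Differences between weeks were tested directly. Of the 59 genes that differed between weeks 1 and 2, those named in the text were C1qtnf3 (1.85), Ccl17 (-2.16), Ccl2 (-1.12), Ccl21a (0.91), Ccl7 (-2.52), Cldn4 (-1.71), Crem (0.80), Dbp (-3.12), Emcn (0.55), Fam124b (1.65), Igfbp3 (2.39), Nr1d1 (-1.94), Nr1d2 (-1.89) and Pcolce2 (1.46), as log2 changes of week 2 minus week 1. Lists that differed at a preset correlation, given as medians, were matrix glycoproteins (0.26), monocyte-derived macrophages (-0.42), dendritic cells (-0.64), chemokines and cytokines (-0.47), interferon response (-0.41), proliferation (-0.58), injury-associated epithelium (-0.33), endothelium (0.37), red blood cells (1.06) and circadian clock (-0.44). Of the 24 from week 2 to week 5, those named were Ccn4 (-1.54), Cdk1 (-2.16), Col5a1 (-0.90), Cry2 (1.03), Gtse1 (-1.89), Lox (-1.34), Nr1d1 (1.80), Prc1 (-1.90), Serpina3n (-1.05), Spag5 (-2.15) and Thrap3 (1.37). The lists were fibrillar collagens (-0.43), basement membrane (-0.28), collagen folding and crosslinking (-0.21), matrix glycoproteins (-0.31), matrix-degrading proteases (-0.37), monocyte-derived macrophages (-0.58), chemokines and cytokines (-0.21), p53 targets (-0.31), proliferation (-0.82), club cells (0.37), ciliated cells (0.33), heart and skeletal muscle (0.69) and circadian clock (0.46). New collagen formation changed by -7.55 percentage points. With an estimated correlation 1 list passed between weeks 1 and 2 and 0 from week 2 to week 5.

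Clock genes differed between weeks 1 and 2: the mean of Arntl, Clock and Npas2 was 1.07 log2 higher in week 2 (exact permutation p = 0.00117, 95% limits 0.652 and 1.484) and that of Per3, Tef and Hlf 0.82 lower (exact p = 0.00991), apart from Dbp, Nr1d1 and Nr1d2, whose fall prompted the test. The first mean minus that of all 6 others was 2.63 higher (adjusted p = 0.0035 over 6 comparisons), and against control it was -1.46 at week 1 (adjusted p = 0.0455), 1.17 at week 2 and 1.22 at week 4 (adjusted p = 0.0594 for both). The 6 others include Dbp, Nr1d1 and Nr1d2, so the size and p of this measure partly restate the fall that prompted the test. Collection at another time of day needs such opposite movement and may be the source, and the labels give no hour. A changed share of infiltrating cells is argued against, since with the macrophage, T cell and proliferation list means as covariates the difference was 2.88 (95% limits 2.12 and 3.64, against 1.32 for 0.5 of the first value). The control animals spanned -1.67 to 2.45 on the same measure, so they too may have been collected at several hours, and an effect of bleomycin on the clock stays open.

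Contractile genes fell while Tnc and collagen genes rose. Dilution by infiltrating cells would lower endothelial and alveolar genes as much. Alveolar genes exceeded the contractile list by 0.70 (exact p = 0.000583), 0.69 (exact p = 0.00233) and 0.73 (exact p = 0.00117) log2 at weeks 1, 2 and 3. This argues against a dilution of all resident cells alike as the whole cause. The alveolar type 2 list as fixed shares Fabp5 with the macrophage list, so infiltrating cells may hold up part of this margin. It was the larger of the 2 margins and was taken after both were seen. Endothelial genes exceeded the contractile list by 0.24 (exact p = 0.206), 0.53 (exact p = 0.0315) and 0.50 (exact p = 0.0111), so at week 1 a loss shared by vessel cells and muscle stays open. Airway lists fell about as much as the contractile list, whose medians at weeks 1, 2 and 3 were -0.59, -0.65 and -0.60. Medians were -0.83, -0.75 and -0.74 for club cell genes and -0.55, -0.75 and -0.91 for ciliated cell genes. A loss shared by airways and muscle was not tested and stays open at weeks 1, 2 and 3. Probes shared between actin genes are argued against, as 7, 5 and 5 of the 10 contractile genes other than actins were lower at weeks 1, 2 and 3. A loss of smooth muscle transcripts, alone or together with airway transcripts, may be what remains.

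Genes followed new collagen formation among animals of the same week. A larger share of infiltrating macrophages in the more fibrotic animals could be part of this: with the macrophage list mean as a covariate the slopes kept a median of 0.66 of their size (quartiles 0.491 and 0.82) and 4 genes passed, which decides neither way. Without the 2 animals farthest from the median, the median ratio of the slopes was 1.02 (quartiles 0.811 and 1.21) and 738 of 738 genes kept their sign. The genes were picked on the slope over all arrays, which by itself favours a kept size and sign. This test therefore cannot tell whether the 2 animals make the slopes. The calls did rest on these 2 animals, since 17 genes passed without them.

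In 100 splits of the same arrays, the real one included, the share with as many genes was under 0.05 for each count, the limit set before. That share was not adjusted over the 10 counts. For weeks 2, 4 and 5 against control and week 5 against week 2 another split called more genes than the real one, so chance is not excluded there. Week 1 against control had 2145 genes and the highest other split 1346, week 2 had 1611 and 1623, week 3 had 1033 and 569, week 4 had 480 and 577, and week 5 had 11 and 35, with 1, 2, 1, 2 and 2 splits as large as the real one. Week 2 against week 1 had 59 and 18 (1 split), week 5 against week 2 had 24 and 81 (2 splits), the joint test 1713 and 1 (1 split), new collagen over all arrays 3068 and 1 (1 split) and within time points 738 and 48 (1 split). For new collagen over all arrays the values were shuffled across groups, so differences between groups alone can give this outcome. It therefore tells nothing of a relation within groups. For week 5 against control and against week 2 the 1 other split as large called several times the real count. This may point to a structure among the animals that the groups do not describe. No direct test of one was run, and the counts between groups rose with replicate number as a block.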

How the results depend on the processing

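The filter on a mean log2 of at least 5 and the omission of the least correlated array of each group were chosen after seeing the data. With array quality weights the counts were 736 genes at week 4, 217 at week 5, 64 from week 2 to week 5 and 316 with new collagen within time points, against 480, 11, 24 and 738. With replicate number as a block they were 56 at week 5, 144 between weeks 1 and 2, 63 from week 2 to week 5 and 350 within time points. The other group counts rose too, to 2537, 1891, 1417 and 695 at weeks 1 to 4 and 2272 in the joint test. New collagen formation at week 5 then exceeded control by 1.53 (adjusted p = 0.146, exact test on differences paired by replicate number). The labels do not say whether animals of equal number share a batch, so the source of this rise in counts is not known. Without the least correlated arrays they were 186 at week 4, 162 at week 5, 34 between weeks 1 and 2, 114 from week 2 to week 5 and 213 within time points. With only the 2 groups compared they were 271 at week 4, 3 at week 5, 9 between weeks 1 and 2 and 2 from week 2 to week 5. At week 5 the filter on dim genes gave 18 and all probes 36. Over weeks 1 to 5 alone, 1643 genes followed new collagen, and without the 2 animals farthest from the median 17 did within time points. Lists past the threshold went from 152 to 28 with an estimated correlation. Of 195 named changes past the threshold 190 passed with weights and 179 without the least correlated arrays, and Col1a1 at weeks 1 and 3, Ager at week 3 and Fam124b between weeks 1 and 2 passed in neither. With the filter on dim genes 159 passed. None of the named changes that it kept lost the threshold, and the rest were of genes too dim for it.

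Leaving out 1 array gave 1032 to 1927 genes for week 2 (1032 without week 2 replicate 2, 1068 without week 2 replicate 4), and for week 3 388 to 1139 (388 without week 3 replicate 3, 630 without control replicate 2). Week 4 ranged from 98 to 717: 98, 172, 249, 285 and 311 without week 4 replicates 4, 3, 6, 2 and 5, and 127, 280 and 280 without control replicates 2, 1 and 7. Week 5 ranged from 2 to 130: 2, 3, 6 and 130 without week 5 replicates 5, 3, 4 and 2, and 3, 5, 5, 6, 27 and 33 without control replicates 2, 1, 3, 7, 6 and 4. Between weeks 1 and 2 the range was 28 to 136, with 28, 28, 35, 100 and 136 without week 2 replicates 1, 6, 4, 2 and 3 and 35 without week 1 replicate 1. From week 2 to week 5 it was 3 to 176, with 3, 4, 9 and 176 without week 2 replicates 2, 3, 4 and 5 and 5, 11 and 11 without week 5 replicates 4, 2 and 6. Within time points it was 85 to 839, with 85 and 480 without week 3 replicates 3 and 2. The difference in new collagen between weeks 2 and 1 went from -0.54 without week 2 replicate 2 to 2.05 without week 2 replicate 1. Week 1 (1819 to 2320), the joint test (1328 to 1916) and new collagen over all arrays (2650 to 3169) stayed within 1.5 times. Not run, because the scanner table was not used, were another background correction, median scaling without quantile normalization, detection filters and the slide as a block, and the comparison with the authors' own table, which is the table analysed.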

Other observations

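The tests of the contractile genes and the test of collection at another time of day, which this part refers to, were chosen after the results were seen.

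Col4a3, a type IV collagen chain, was above control in each week. It was higher by 0.87 ± 0.23 (log2 change ± SE), 1.56 ± 0.24, 1.52 ± 0.24, 1.40 ± 0.24 and 1.12 ± 0.24 at weeks 1 to 5, past the threshold at each, while Col1a1 passed at weeks 1 and 3 alone and Col3a1 was at 0.84 at week 1. The direct tests between weeks did not pass for Col4a3, and how long a change lasts was not compared between genes. Of basement membrane genes at week 5, 1 of 17 rose and 0 fell (5 and 1 adjusted over the list alone) (median 0.21, list adjusted p = 0.0166, and adjusted p = 0.347 with an estimated correlation), and the week 5 count ran from 2 genes without week 5 replicate 5 to 130 without week 5 replicate 2. Col4a3, Col4a4 and Col4a5 form the mature network under alveolar and glomerular epithelium, while Col4a1 and Col4a2 are found in most basement membranes.

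Lymphocyte and dividing cell genes had different courses of their medians, a contrast that was not tested. Proliferation genes had a median of 1.05 at week 2 and -0.03 at week 5, and fell between them at the preset correlation (median -0.82, list adjusted p = 1.17e-17, and adjusted p = 0.0946 with an estimated correlation). B and plasma cell genes had medians of 0.61, 0.85, 0.87, 0.76 and 0.93, with no difference past the threshold between weeks 2 and 5. With an estimated correlation their list passed in no week (adjusted p = 0.344, 0.152, 0.163, 0.157 and 0.144). At week 5, 0 of 10 of them passed over all genes. Ccl21a, which draws lymphocytes into lymphoid tissue, was higher at week 5. Persistent lymphoid aggregates may account for the B cell medians and Ccl21a. However, the count of 11 genes at week 5 was 217 with array quality weights, so the week 5 calls depended on the fit. Counting B cells and follicles in sections at weeks 3 and 5 would test it.

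Smooth muscle genes such as Acta2 and Myh11 did not rise with collagen in whole lobe RNA. Airway and vessel muscle may hide a smaller number of myofibroblasts. At weeks 2 and 3 endothelial genes exceeded the contractile list by 0.53 and 0.50 and alveolar genes by 0.69 and 0.73. This argues against a dilution of all resident cells alike as the whole cause, although infiltrating cells may hold up part of the alveolar margin. Club and ciliated cell lists fell about as much as the contractile list, so a loss shared by airways and muscle stays open. Staining for Acta2 in airway walls and in scars, counted apart, would separate a loss of airway muscle from a gain in scars.

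Gsta3 and Adipoq fell, and Eln, Timp1 and Ccn4 rose, with new collagen formation beside the group means. The slopes kept a median of 1.02 of their size without the 2 animals farthest from the median, which picking the genes on all arrays favours. Only 17 of 738 genes passed without these animals. With the macrophage list as a covariate the slopes kept 0.66 and 4 genes passed. These genes were picked for their statistic in the same data, and within week 5 r was -0.243 for Eln, -0.056 for Timp1, 0.142 for Ccn4, 0.001 for Gsta3 and -0.124 for Adipoq. A use as a readout of matrix synthesis was therefore not shown. Sorting fibroblasts and macrophages from animals labelled with deuterated water, and relating each cell type's transcripts to the collagen value, would show which cells carry the relation.

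The mean of Arntl, Clock and Npas2 was 1.07 log2 higher at week 2 than at week 1, and that of Per3, Tef and Hlf 0.82 lower. Dbp, Nr1d1 and Nr1d2 in that comparison may reflect the hour of collection or an effect of bleomycin on the clock, which no test here separates. Repeating weeks 1 and 2 with killing at 1 fixed hour would decide it.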
